A study of Mus musculus with 8 samples.

How the data were processed

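The samples were male mouse induced pluripotent stem cells from 2 independent clones, grown on irradiated feeder cells in serum with LIF and 2 kinase inhibitors, per the labels' protocols. For synchronisation, cells were passaged to gelatin, arrested with nocodazole at 200 ng/ml for 6 h, collected by shake-off and plated on gelatin for 1 h or 3 h, per the labels' protocols. The protocol for RNA extraction in the labels names asynchronous cells only, and the steps used for the other states are not given in the sources used here. The 8 libraries were made with a strand-marking kit that selects poly(A) RNA and were sequenced as single reads of 50 bases, per the labels' protocols. TopHat2, SAMtools, HTSeq and the genome build mm10 are named, without versions, roles or settings, per the submitters' processing notes, and the annotation release and strand setting of the counting are not given in the sources used here.

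The authors deposited raw counts of reads per Ensembl gene for 54838 genes and 8 samples, whole numbers without normalisation. Of these genes 20402 had 0 counts in every library. The table held 0 counts on the mitochondrial chromosome, so a list of mitochondrially encoded genes, fixed with 21 others before the data were examined, could not be tested. Gene IDs were matched to symbols, biotypes and coordinates with the GENCODE M21 annotation of GRCm38 (mm10), which gave a symbol for 54723 IDs (99.8%). Coordinates are 1-based. Since the strand setting is unknown, values of antisense and overlapping genes are uncertain, as are those of genes with near-identical copies such as the Zscan4 family, histones and ribosomal proteins.

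Total counts ranged from 20410621 to 25615244 per library. A floor of 3 counts corresponded to between 0.116 and 0.152 CPM, and such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Samples were grouped by their titles into 4 states of 2 libraries. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were filtered with filterByExpr (minimum count 10), which left 19101, libraries were scaled by TMM, and the quasi-likelihood test with robust dispersion was fitted to all 8 libraries without a replicate block (4 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no minimum fold. Every test was two-sided. Levels are TMM-normalised CPM. Adjusted p of a gene is from edgeR throughout unless another tool is named.

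Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with the correlation between genes preset to 0.01 and lists of at least 5 tested genes, adjusted over the 21 lists within a comparison. The tests were repeated with an estimated correlation and with fry. The lists were core and naive pluripotency, formative and primed pluripotency, germ layer and extraembryonic lineage, two-cell-like, G2 and M phase, G1 to S phase, immediate early, p53 targets, tubulins, heat shock, integrated stress response, cholesterol synthesis, glycolysis and hypoxia, ribosome biogenesis, LIF and STAT3 targets, Wnt targets, actin and SRF or YAP targets, cohesin with condensin, CTCF and acetylation readers and writers, feeder fibroblast markers, replication-dependent histones and ribosomal proteins.

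The genes named were set by a rule before the data were examined. In each of 4 main comparisons it took the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 2, both libraries of one group above both of the other and a symbol that is no clone name or pseudogene, the 3 members with the smallest p of each called list in its direction, and Pou5f1, Sox2, Nanog, Esrrb, Klf4, Ccnb1, Plk1, Ccne1 and Myc. For overlaps it took the 3 genes of each direction with the largest smaller change. No gene passed the rule between early and late G1, so the same rule was applied there to the fit of those 2 groups alone. Some genes that the rule took are not reported here. Genes that differ between replicates, the macrophage markers and the lists of the closing section were chosen after the data had been examined.

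The tests were tested on simulated data drawn from the means and library sizes of the real genes. Each gene had the same spread in all simulated libraries. The real biological coefficient of variation ran from 0.0417 in late G1 to 0.292 in asynchronous cells, so the rates need not hold for the real groups. In each comparison 100 genes were changed 2-fold and 100 changed 4-fold. Of these, 39 and 73 were called for mitotic against asynchronous cells (18524 genes tested, 11 false calls), 34 and 70 for early G1 against mitotic cells (18518 genes, 5 false calls), 45 and 77 for late G1 against early G1 (18523 genes, 16 false calls), 44 and 73 for late G1 against mitotic cells (18553 genes, 3 false calls), 43 and 83 for late G1 against asynchronous cells (18527 genes, 11 false calls) and 44 and 79 for early G1 against asynchronous cells (18532 genes, 19 false calls). The calls in all, in the same order, were 123, 109, 138, 120, 137 and 142. In a simulated comparison of early G1 with mitotic cells, a list shifted by 0.5 on the log2 scale was called and 0 of the 20 others.

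Alternatives tried were the size factors of DESeq2, scaling by total counts only, DESeq2 1.42.0, limma voom, no filter on low counts, a filter of 1 CPM in 2 samples, fits of the 2 groups compared alone, the replicate number as a block, and leaving out each library in turn, which leaves 1 library in a group whose spread is then assumed to be that of the other groups. A term that sets replicate 1 of the mitotic and asynchronous groups apart, leaving out both of these libraries, and lists without feeder genes were added after the data had been examined. Leaving out both leaves 1 mitotic and 1 asynchronous library, so all spread then comes from the G1 libraries. Counts and p-values of that fit therefore do not measure the spread of mitotic or asynchronous cells. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.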

Results

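Messenger RNA was sequenced from male mouse induced pluripotent stem cells, reprogrammed cells that grow and differentiate much as embryonic stem cells do (the sample labels call them ESC), in 4 states of the cell cycle. Asynchronous cells came from a cycling population. Mitotic cells had been held for 6 h in nocodazole at 200 ng/ml, a drug that stops microtubule growth and arrests cells in mitosis, and were shaken off the plate. Early G1 and late G1 cells were collected 1 h and 3 h after the drug had been washed out. Each state had n = 2 libraries, 8 in all, and per the labels 2 independent clones served as biological replicates, so p-values measured the spread between 2 clones or between the samples taken from them. Total counts were 24188305 and 20410621 in the asynchronous libraries and 24476915 and 23471553 in the mitotic ones. They were 21067481 and 25615244 in early G1 and 21688413 and 21182167 in late G1. The question set by the design was which transcripts differed at the arrest, which changed in the first hour and by 3 h after release, and which still differed from cycling cells at that point. Levels are given as CPM, counts scaled to a common library size, mean ± SD of n = 2 libraries, and changes as log2 fold changes. Of 54838 genes in the table, 19101 had enough counts to be tested, and 9265 of these differed between any of the 4 states (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05).

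The first principal component of the log2 CPM values held 59.7% of the variance and placed the asynchronous libraries (-95.3 and -120.8) apart from the other 6, which lay between 16.6 and 49.98. The second held 18.4% and placed the mitotic libraries (-62.2 and -58.1) apart from early G1 (19.4 and 24.6) and late G1 (28.1 and 25.4). The spread between replicates was uneven. The biological coefficient of variation was 0.292 in asynchronous cells, 0.183 in mitotic cells, 0.0506 in early G1 and 0.0417 in late G1. Replicate 1 differed from replicate 2 alike in the asynchronous and mitotic groups, with a correlation of 0.621 between the replicate deviations of 12037 genes, which are not independent replicates. Transcripts of the Y chromosome were among the genes that differed. Eif2s3y, a translation initiation factor gene, stood at 91.6 and 28.4 CPM in asynchronous replicates 1 and 2, at 82.0 and 28.8 CPM in the mitotic ones, and between 28.8 and 32.5 CPM in the 4 G1 libraries. In early and late G1 only 7 and 8 of the 12037 genes differed by more than 2-fold between replicates, against 774 in asynchronous and 194 in mitotic cells. No pair of replicates agreed within sampling noise, the mean chi-square per gene being at least 3.00.

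**Figure D1:**
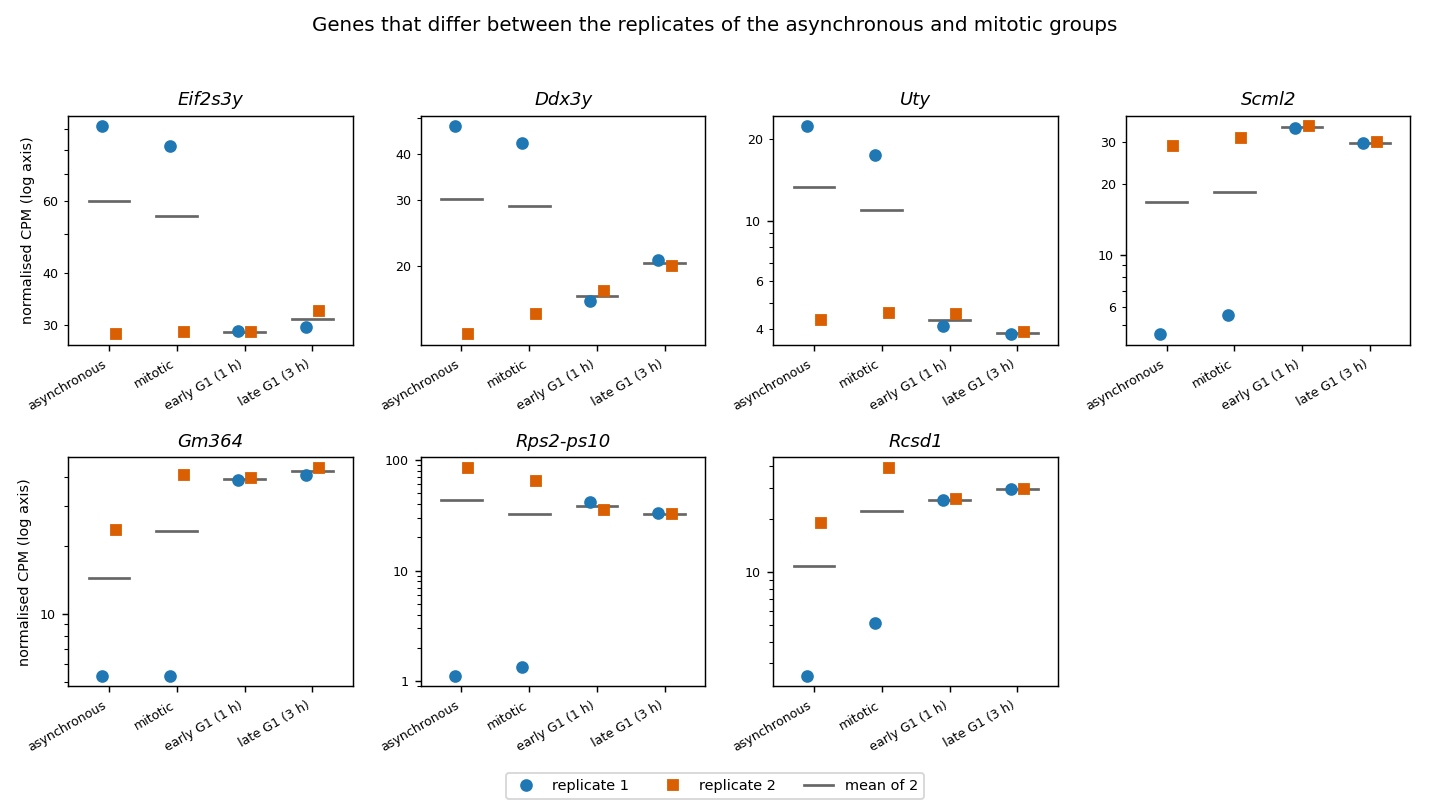
Normalised CPM (log axis) of 7 genes in each of the 8 libraries, replicate 1 as circles, replicate 2 as squares and the mean of both as a line. The genes were chosen after their values were seen. In the asynchronous and mitotic groups the replicates lie apart in every panel (Eif2s3y 91.6 and 28.4 CPM in asynchronous cells), and in early and late G1 they lie close together.

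Mitotic cells carried more transcript of several regulators of pluripotency than asynchronous cells. Myc (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374, GRCm38), a growth-promoting transcription factor gene, rose 7.38-fold (17.2 ± 6.10 against 2.26 ± 1.70 CPM, adjusted p = 0.00180). Klf4 (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466) rose 2.29-fold (173 ± 28.4 against 75.3 ± 12.7 CPM), Esrrb 1.85-fold and Nanog 1.54-fold, all transcription factors of the naive pluripotent state. Pou5f1 stood at 2091 ± 42.7 against 1772 ± 423 CPM and Sox2 at 251 ± 11.1 against 281 ± 42.9 CPM, and neither was called (adjusted p = 0.264 and 0.367). Asynchronous replicates 1 and 2 lay apart, at 1472 and 2071 CPM for Pou5f1 and 312 and 251 CPM for Sox2. The mitotic levels were nearer to replicate 2, so these results depended on the asynchronous library. Among 30 core and naive pluripotency genes, 18 rose, 4 fell and 8 were not called (19 and 4 adjusted over the list alone). For core and naive pluripotency, camera gave adjusted p = 1.44e-04, or adjusted p = 0.179 with an estimated correlation. Nr0b1, Dppa2 and Zfp57 rose 5.84-, 3.26- and 2.27-fold. Of the mitotic cyclin and kinase genes Ccnb1 fell by 0.71 on the log2 scale (84.2 ± 0.926 against 138 ± 2.37 CPM, adjusted p = 0.00189), while Plk1 was not called (158 ± 5.95 against 137 ± 10.6 CPM), and Ccne1, the cyclin of the G1 to S transition, rose 1.67-fold.

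Genes of glycolysis and of the response to low oxygen were lower in mitotic than in asynchronous cells: of 29 gene IDs tested, 2 of them named Aldoa, 0 rose and 27 fell (28 adjusted over the list alone), with a median of -1.71, camera adjusted p = 7.81e-16, and adjusted p = 0.0341 with an estimated correlation. Ndrg1 (ENSMUSG00000005125, chromosome 15, 66929318 to 66969640) fell from 308 ± 25.2 to 30.8 ± 3.93 CPM, and Bnip3, a mitophagy receptor gene, from 106 ± 14.4 to 12.3 ± 0.301 CPM. Genes of ribosome biogenesis went the other way: 27 of 40 rose and none fell (29 and 1 adjusted over the list alone), with camera adjusted p = 3.48e-09 and adjusted p = 0.0341 with an estimated correlation. They included Ddx21, a nucleolar RNA helicase gene (612 ± 39.9 against 203 ± 49.7 CPM), and Polr1b, a subunit gene of RNA polymerase I (193 ± 1.55 against 87.4 ± 8.05 CPM). Fibroblast markers, listed because the cells are grown on irradiated feeder cells, moved with the same groups: of 25, 0 rose, 23 fell and 2 were not called (0 and 23 adjusted over the list alone). For feeder fibroblast markers, camera gave adjusted p = 6.26e-15, or adjusted p = 0.0566 with an estimated correlation. Their summed level was 1905 and 1933 CPM in the asynchronous libraries, 122 and 114 CPM in the mitotic ones and 81.5 to 155 CPM in G1. Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), fell from 532 ± 32.0 to 8.87 ± 1.81 CPM, and Postn, which encodes periostin, from 92.4 ± 12.5 to 0.896 ± 0.0153 CPM. Per the labels, cells were moved from feeders to gelatin before the arrest. The handling for synchronisation, the drug and feeder RNA all set the asynchronous libraries apart from the others. Comparisons with asynchronous cells cannot tell these apart from the state of the cell cycle.

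The 6 largest falls in mitotic cells under the rule for named genes were those of Adm, a hypoxia-induced peptide hormone gene (-6.95), of the matrix gene Tnc (-6.78), and of the feeder markers Postn (-6.68), Lox (-6.44), Col1a2 (-6.39) and Thbs2 (-6.37). The largest rises under it included those of Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), a cytochrome P450 gene induced through the aryl hydrocarbon receptor (7.42 ± 2.63 against 0.130 ± 0.0409 CPM, log2 5.74, SE 0.40), of the chloride channel gene Ano1 (4.45), of Synpo2l (3.96), Enox1 (3.86) and Nt5e (3.55).

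Other list changes between mitotic and asynchronous cells were called with the preset correlation and lost with an estimated one. Among 18 heat shock genes, 10 rose, 2 fell and 6 were not called (10 and 2 adjusted over the list alone). For heat shock, camera gave adjusted p = 0.0102, or adjusted p = 0.611 with an estimated correlation. The chaperone genes Hsph1 and Dnaja1 rose 3.65- and 2.48-fold. Among 28 genes of the integrated stress response, 3 rose, 11 fell and 14 were not called (3 and 11 adjusted over the list alone). For integrated stress response, camera gave adjusted p = 0.00645, or adjusted p = 0.611 with an estimated correlation. Ddit3, Ddit4 and Stc2 fell, with log2 changes of -2.57, -3.09 and -4.21. Among 50 G1 to S genes, 15 rose, 5 fell and 30 were not called (15 and 5 adjusted over the list alone). For G1 to S phase, camera gave adjusted p = 0.0341, or adjusted p = 0.179 with an estimated correlation. Mcm2, a subunit of the replicative helicase, stood at 694 ± 12.2 against 420.1 ± 5.11 CPM and Ccnd1 and Exo1 1.92- and 1.78-fold higher. Among 30 genes of cohesin, condensin, CTCF and acetylation, 11 rose, 3 fell and 16 were not called (11 and 3 adjusted over the list alone). For cohesin and acetylation, camera gave adjusted p = 0.0102, or adjusted p = 0.611 with an estimated correlation. Yy1, Hdac2 and Hdac1 rose 1.78-, 1.54- and 1.49-fold. Among 18 two-cell-like genes, expressed in the rare cells that resemble the cleavage embryo, 5 rose, 0 fell and 13 were not called (5 and 0 adjusted over the list alone). For two-cell-like, camera gave adjusted p = 0.0136, or adjusted p = 0.611 with an estimated correlation. Usp17le rose 4.02-fold. The list also holds Eif1a, which rose 1.63-fold but stood at 184 CPM or more in every library, so it was not confined to rare cells. Among 83 ribosomal protein genes, 2 rose, 42 fell and 39 were not called (2 and 43 adjusted over the list alone). For ribosomal proteins, camera gave adjusted p = 6.88e-07, or adjusted p = 0.611 with an estimated correlation. Rpl12 fell from 488 ± 62.3 to 207 ± 9.76 CPM. Among 29 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 0 rose, 9 fell and 20 were not called (0 and 3 adjusted over the list alone). For histones, camera gave adjusted p = 0.0386, or adjusted p = 0.611 with an estimated correlation, at levels such as 0.127 ± 0.0581 against 1.68 ± 0.349 CPM for Hist1h1b. In the fit of these 2 groups alone the counts of called members were lower: 5 higher and 1 lower among G1 to S genes, 2 and 1 among cohesin and acetylation genes, 5 and 1 among heat shock genes, 2 and 0 among two-cell-like genes, 1 and 17 among ribosomal protein genes, 0 and 2 among histones and 12 and 2 among core and naive pluripotency genes. With a term for replicate 1 of the mitotic and asynchronous groups they were 21 and 8 for G1 to S, 17 and 4 for cohesin and acetylation, 9 and 0 for two-cell-like genes, 0 and 14 for histones and 5 and 16 for the integrated stress response.

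The other 10 lists were not called between mitotic and asynchronous cells (camera adjusted p from 0.0533 for cholesterol synthesis to 0.699 for Wnt targets). Median and mean of a list differed in sign for G2 and M phase genes (0.23 and -0.11), LIF and STAT3 targets (0.25 and -0.051), actin and SRF or YAP targets (0.22 and -0.28) and formative and primed pluripotency genes (0.0016 and -0.11), and p53 targets ranked upward in the test with a median of -0.023. In all, 7767 genes were called, 3487 higher and 4280 lower in mitotic cells, and 1433 and 2828 of these changed by at least 2-fold. Without 1 library, calls were lost for Ccne1 (adjusted p = 0.0507 without mitotic replicate 2), for Hist3h2ba (adjusted p = 0.0742 without mitotic replicate 1) and for Zfp352 (adjusted p from 0.0517 to 0.111 without asynchronous replicate 2, either mitotic library or late G1 replicate 2). Without asynchronous replicate 1, heat shock and G1 to S had camera adjusted p = 0.110 and 0.0564. Without asynchronous replicate 2, two-cell-like, cohesin and histone lists had 0.126, 0.201 and 0.471. The fit of these 2 groups alone called 3883 genes, 3870 of them among the 7767. In that fit Ccne1, Hdac1, Hist3h2ba and Zfp352 lost their calls (adjusted p = 0.0521, 0.0732, 0.0656 and 0.0516), the last 2 also by DESeq2 (adjusted p = 0.0588 and 0.0903). The count was 4737 without mitotic replicate 1. A term that set replicate 1 of the mitotic and asynchronous groups apart gave 11017 genes, and the histone list lost its call (camera adjusted p = 0.0510). Leaving out both of these libraries gave 11700 genes, and the two-cell-like and heat shock lists lost theirs (0.0712 and 0.0503).

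**Figure D2:**
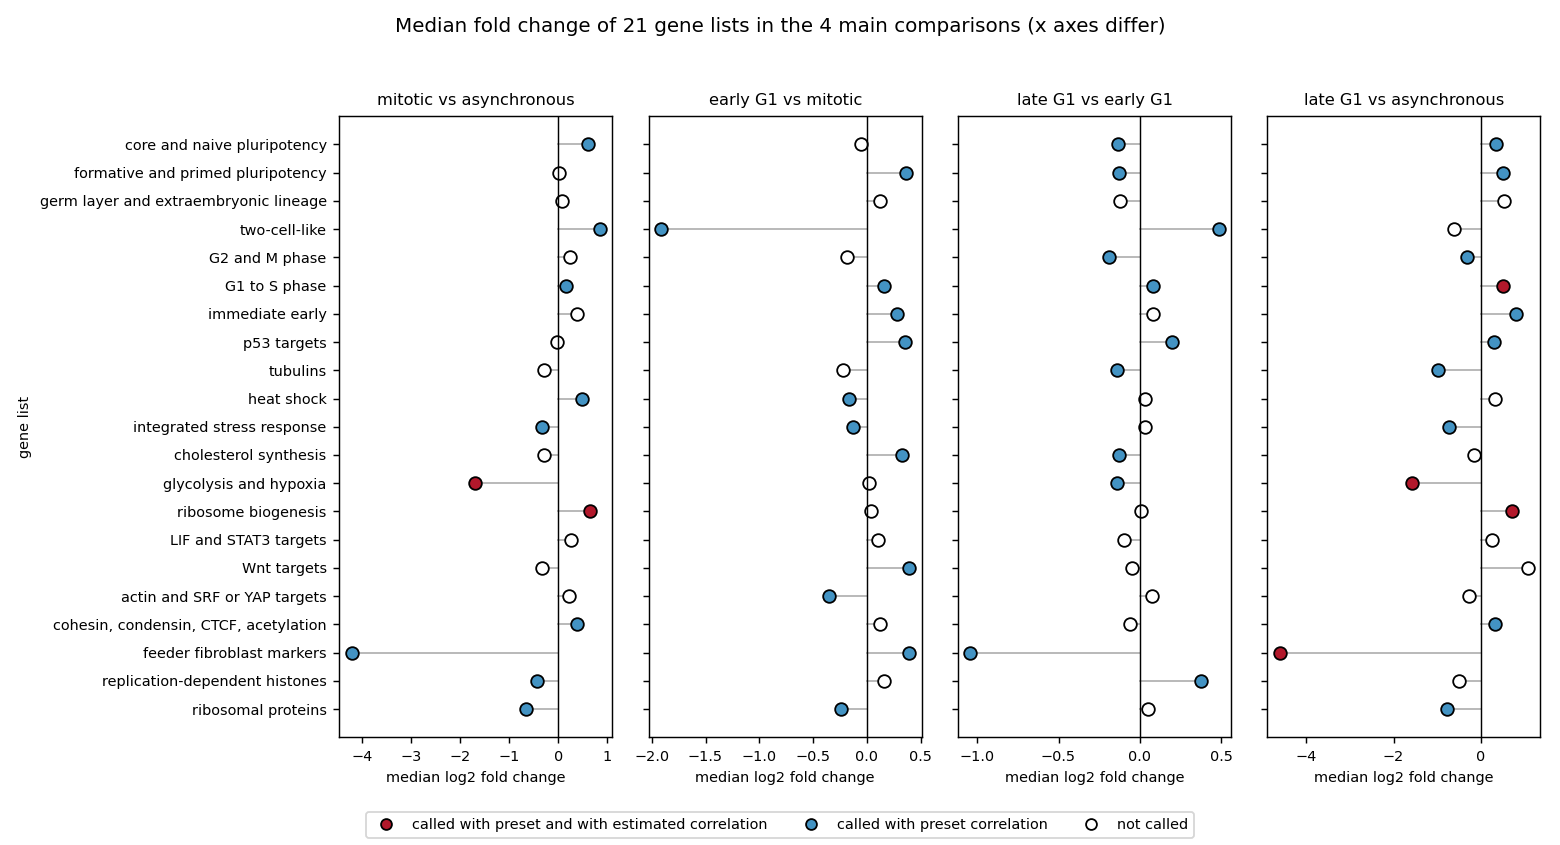
Median log2 fold change of the tested members of 21 gene lists (points) in 4 comparisons, with x axes that differ between panels. Dark red points were called by camera with the preset and with an estimated correlation, blue points with the preset correlation only, and open points were not called. The feeder fibroblast markers have the lowest medians against asynchronous cells (-4.22 and -4.61).

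In the first hour after release, 885 genes were called, 613 higher and 272 lower than in mitotic cells, and 439 and 166 of these changed by at least 2-fold. Egr1 (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), an immediate early transcription factor gene, rose 12.7-fold (12.2 ± 0.976 against 0.958 ± 0.195 CPM, adjusted p = 9.78e-04). Fbxo5 (ENSMUSG00000019773, chromosome 10, 5799160 to 5805600), which encodes an inhibitor of the anaphase-promoting complex, rose 7.14-fold (89.2 ± 1.99 against 12.5 ± 0.274 CPM), and Cry2, a circadian repressor gene, 5.90-fold (40.4 ± 0.574 against 6.83 ± 1.24 CPM). Pou2f3 (log2 2.96), Spin4 (2.71) and the matrix gene Tnc (3.28) were the other largest rises under the rule for named genes. Neat1, the long noncoding RNA of paraspeckles, fell from 162 ± 15.3 to 38.5 ± 1.07 CPM, and Rtl1 and Adamtsl5 fell, with log2 changes of -1.70 and -2.05. In the fit of all 4 groups, none of the 9 regulators followed in every comparison was called between mitotic cells and early G1: Myc stood at 42.4 ± 1.62 against 17.2 ± 6.10 CPM (adjusted p = 0.0956), Ccnb1 at 114 ± 1.12 against 84.2 ± 0.926 CPM (adjusted p = 0.0652) and Pou5f1 at 1858 ± 137 against 2091 ± 42.7 CPM, and adjusted p of the other 6 was at least 0.141. Of 55 genes named in this comparison, 38 were called. Other fits called some of the rest: 7 in the fit of these 2 groups alone, 7 with a term for replicate 1 of the mitotic and asynchronous groups and 5 by DESeq2. Some of the 9 regulators may be among them.

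Genes of formative and primed pluripotency, the states that follow the naive one, went up in this first hour: of 19, 6 rose, 0 fell and 13 were not called (6 and 0 adjusted over the list alone). For formative and primed pluripotency, camera gave adjusted p = 3.11e-04, or adjusted p = 0.157 with an estimated correlation. Nodal, a TGF-beta family ligand gene, rose from 59.4 ± 4.82 to 184 ± 5.70 CPM, Foxd3 from 7.03 ± 0.362 to 28.9 ± 1.33 CPM and Spry4, a feedback inhibitor of ERK signalling, from 7.92 ± 1.92 to 43.2 ± 1.87 CPM. Two-cell-like genes went down: of 18, 1 rose, 8 fell and 9 were not called (1 and 14 adjusted over the list alone). The 1 that rose was Ddit4l, which is also on the p53 list. For two-cell-like, camera gave adjusted p = 2.17e-08, or adjusted p = 0.151 with an estimated correlation. Zscan4d (ENSMUSG00000090714, chromosome 7, 11161374 to 11166159) fell from 9.05 ± 1.08 to 1.84 ± 0.731 CPM, and Zscan4c and Tcstv1 fell, with log2 changes of -2.48 and -2.56. These genes have near-identical copies among which reads could have been split, so values of single members are uncertain. Among 50 G1 to S genes, 5 rose, 0 fell and 45 were not called (7 and 0 adjusted over the list alone). For G1 to S phase, camera gave adjusted p = 3.11e-04, or adjusted p = 0.116 with an estimated correlation. Ccne2, a cyclin of S phase entry, stood at 38.9 ± 0.164 against 10.8 ± 0.811 CPM and Dtl at 181 ± 3.51 against 88.6 ± 1.17 CPM. Among 29 immediate early genes, 5 rose, 1 fell and 23 were not called (8 and 2 adjusted over the list alone). For immediate early, camera gave adjusted p = 0.00369, or adjusted p = 0.288 with an estimated correlation. Junb and Ier5 rose 2.32- and 2.42-fold. Among 30 p53 targets, 5 rose, 1 fell and 24 were not called (6 and 1 adjusted over the list alone). For p53 targets, camera gave adjusted p = 6.89e-04, or adjusted p = 0.183 with an estimated correlation. Pmaip1, a pro-apoptotic gene, rose to 106 ± 1.04 from 50.9 ± 5.21 CPM and Plk2 to 178 ± 2.27 from 89.1 ± 9.36 CPM.

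Cholesterol synthesis genes also ranked upward in early G1: of 25, 4 rose, 0 fell and 21 were not called (7 and 0 adjusted over the list alone). For cholesterol synthesis, camera gave adjusted p = 3.11e-04, or adjusted p = 0.116 with an estimated correlation. Insig1 stood at 117 ± 0.554 against 63.5 ± 11.2 CPM. Among 17 Wnt targets, 1 rose, 1 fell and 15 were not called (7 and 1 adjusted over the list alone). For Wnt targets, camera gave adjusted p = 0.00210, or adjusted p = 0.147 with an estimated correlation. Znrf3 rose 2.23-fold, and Cdx1 and Cdx2 had log2 fold changes of 1.26 and 2.12 and were not called. Actin genes and targets of SRF or YAP ranked downward: of 29, 2 rose, 8 fell and 19 were not called (3 and 13 adjusted over the list alone). For actin targets, camera gave adjusted p = 0.00210, or adjusted p = 0.525 with an estimated correlation. Actg1, cytoplasmic actin, stood at 214 ± 3.63 against 477 ± 54.7 CPM and Cnn2 at 76.6 ± 3.28 against 184 ± 51.0 CPM. Among 28 integrated stress response genes, 0 rose, 3 fell and 25 were not called (1 and 4 adjusted over the list alone). For integrated stress response, camera gave adjusted p = 0.0285, or adjusted p = 0.620 with an estimated correlation. Ddit3, Trib3 and Slc7a11 fell, with log2 changes of -0.83, -1.07 and -1.71. Heat shock genes ranked downward with no member called (camera adjusted p = 0.0465, adjusted p = 0.620 with an estimated correlation). Ribosomal protein genes ranked downward too (median -0.24, camera adjusted p = 0.0322, adjusted p = 0.740 with an estimated correlation), with 5 single members called higher and none lower. In the fit of these 2 groups alone, 8 higher and 16 lower were called, and with a term for replicate 1 of the mitotic and asynchronous groups 9 and 39. Other counts of called members moved in these fits too. The 2 groups alone gave 1 higher and 13 lower among two-cell-like genes, 13 and 0 for G1 to S, 7 and 2 for immediate early genes, 10 and 1 for p53 targets, 9 and 0 for cholesterol synthesis, 6 and 1 for Wnt targets and 3 and 11 for actin targets. The term gave 18 and 4 for G1 to S, 12 and 3 for immediate early genes, 13 and 4 for p53 targets, 12 and 1 for cholesterol synthesis, 6 and 2 for Wnt targets, 7 and 11 for actin targets, 2 and 14 for the integrated stress response and 0 and 6 for heat shock.

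Markers of feeder fibroblasts and of macrophages moved over the same hour. Of 25 fibroblast markers, 4 rose, 0 fell and 21 were not called (6 and 0 adjusted over the list alone). For feeder fibroblast markers, camera gave adjusted p = 0.00289, or adjusted p = 0.288 with an estimated correlation. Col1a1 stood at 19.6 ± 2.71 against 8.87 ± 1.81 CPM. The term for replicate 1 of the mitotic and asynchronous groups gave 7 higher and 0 lower. Lyz2, which encodes the lysozyme of macrophages, fell from 29.7 ± 1.47 to 0.436 ± 0.452 CPM and had 0 counts in both late G1 libraries, at least 214-fold below mitotic cells when 3 counts are taken as the floor of each library. Gpnmb, another gene of macrophages, fell from 22.2 ± 5.57 to 3.33 ± 0.0389 CPM. Of 35 further macrophage markers, a list written after Lyz2 had been seen, 16 were called lower in early G1 than in mitotic cells and 0 higher.

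The other 9 lists were not called between mitotic cells and early G1 (camera adjusted p from 0.0829 for LIF and STAT3 targets to 0.726 for ribosome biogenesis). Median and mean differed in sign for G2 and M phase genes (-0.19 and 0.052) and tubulins (-0.22 and 0.0098). The count of 885 was sensitive to every library. It was 54 without mitotic replicate 1, 144 without mitotic replicate 2, 54 and 42 without early G1 replicates 1 and 2, 228 and 227 without late G1 replicates 1 and 2, and 4431 and 4518 without asynchronous replicates 1 and 2. Of the 38 genes named and called here, 8 were called without each single library in turn: Egr1, Tnc, Cry2, Fbxo5, Lyz2, Neat1, Foxd3 and Nodal. Without mitotic replicate 2, the immediate early, heat shock, integrated stress response and ribosomal protein lists had camera adjusted p = 0.140, 0.172, 0.438 and 0.409. Without early G1 replicate 2 the last 3 had 0.0963, 0.0877 and 0.206. The fit of these 2 groups alone called 2759 genes, 876 of them among the 885, DESeq2 called 1410, no filter on low counts gave 2362, and leaving out replicate 1 of the mitotic and asynchronous groups gave 7918. Scaling by total counts ended the calls of Znrf3 (adjusted p = 0.0537) and of the heat shock list (camera adjusted p = 0.0710), and DESeq2 that of Slc7a11 (adjusted p = 0.119).

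**Figure D3:**
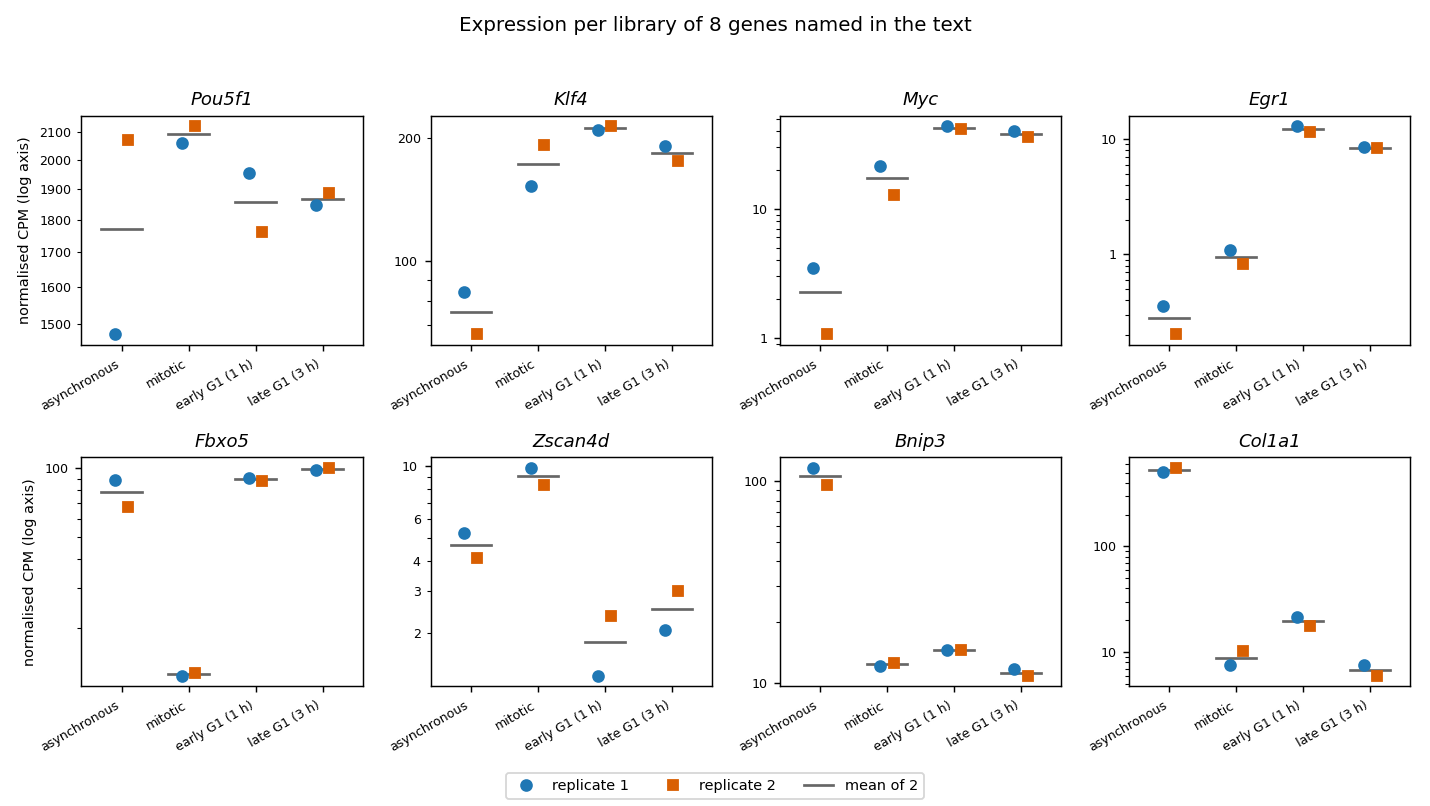
Normalised CPM (log axis) of 8 genes in each of the 8 libraries, replicate 1 as circles, replicate 2 as squares and the mean of both as a line. Fbxo5 is low in the mitotic libraries only (12.5 CPM), Bnip3 and Col1a1 are high in the asynchronous libraries only, and the asynchronous replicates of Pou5f1 lie apart.

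Between early G1 and late G1 no single gene was called by edgeR's quasi-likelihood test over all 8 libraries (smallest adjusted p = 0.0839, for Postn), 724 genes had an unadjusted p under 0.05, limma voom also called 0 genes and DESeq2 called 27. All groups shared 1 estimate of the spread in that test. In the fit of the 4 G1 libraries alone, 619 genes were called higher and 874 lower in late G1. That fit took its spread from replicates with a biological coefficient of variation of 0.0506 and 0.0417. What these libraries were made from is open, so its p-values may not measure the spread between independent clones. The gene count was 23 and 25 without asynchronous replicates 1 and 2, 58 without the filter on low counts, 16 with a term for replicate 1 of the mitotic and asynchronous groups and 1518 without those 2 libraries.

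Genes of G2 and M phase were lower in late G1 as a list: of 62, none was called one by one in the fit of all 4 groups (7 lower adjusted over the list alone), against 0 higher and 32 lower in the fit of the G1 libraries alone and 0 and 5 with a term for replicate 1 of the mitotic and asynchronous groups, with a median of -0.19, camera adjusted p = 1.55e-17 and adjusted p = 0.131 with an estimated correlation. In the fit of the G1 libraries alone, Plk1, a mitotic kinase gene, was lower (82.0 ± 0.717 against 132 ± 4.14 CPM, log2 -0.68, adjusted p = 4.51e-10), as were Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex (73.0 ± 3.68 against 133 ± 6.71 CPM), Nusap1 (46.2 ± 1.18 against 79.5 ± 1.69 CPM) and Arl6ip1 (217 ± 10.4 against 360.5 ± 5.63 CPM). Not all of these genes had been highest in mitosis. The mitotic libraries held Ube2c at 53.6 and 50.8 CPM and Arl6ip1 at 101.5 and 100.1 CPM, below both G1 states. Nusap1, at 63.0 and 52.4 CPM there, lay below early G1 and above late G1. Plk1, at 162.6 and 154.2 CPM there, lay above both G1 states. In the fit of the G1 libraries alone the p53 target Mdm2 was higher (509 ± 1.38 against 347 ± 6.06 CPM), as were Pidd1 (122 ± 5.42 against 88.5 ± 4.36 CPM) and Ddit4l (47.3 ± 1.04 against 27.3 ± 0.0835 CPM). That fit called 14 higher and 3 lower of 30 p53 targets, against 0 in the fit of all 4 groups (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.08e-04, adjusted p = 0.131 with an estimated correlation) and 2 and 0 with the term. Core and naive pluripotency genes ranked downward (median -0.14, 0 of 30 called, 11 lower in the fit of the G1 libraries alone, 1 lower adjusted over the list alone, camera adjusted p = 6.27e-05, adjusted p = 0.131 with an estimated correlation), with Klf2 at 81.8 ± 8.21 against 125 ± 7.40 CPM and Zfp57 at 373 ± 5.46 against 481 ± 1.45 CPM. Pou5f1 stood at 1868 ± 28.2 against 1858 ± 137 CPM and was not called in either fit.

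Several further lists ranked up or down between early and late G1 with no member called over all genes in the fit of all 4 groups. Two-cell-like genes (median 0.48, camera adjusted p = 2.08e-04, adjusted p = 0.217 with an estimated correlation), replication-dependent histones (0.38, 0.00142 and adjusted p = 0.502 with an estimated correlation) and G1 to S genes (0.083, 0.00442 and adjusted p = 0.131 with an estimated correlation) ranked upward. Glycolysis and hypoxia genes (-0.14, 6.27e-05 and adjusted p = 0.131 with an estimated correlation), cholesterol synthesis genes (-0.13, 0.00918 and adjusted p = 0.131 with an estimated correlation), formative and primed pluripotency genes (-0.13, 0.0191 and adjusted p = 0.253 with an estimated correlation) and tubulins (-0.14, 0.0382 and adjusted p = 0.584 with an estimated correlation) ranked downward. Adjusted over each list alone, 1 two-cell-like gene was higher, 1 formative gene was lower and no gene of the other 5 lists was called. The fit of the G1 libraries alone called 12 G1 to S genes and 3 histones (of 17 that it tested) higher and none lower. It called 1 two-cell-like gene (of 10) higher and none lower. That gene was Ddit4l, which is also on the p53 list and is named above as a p53 target. The same fit called 8 glycolysis and hypoxia, 6 cholesterol synthesis and 6 formative genes lower and none higher. Of the tubulins, 2 were higher and 5 lower. With the term for replicate 1 of the mitotic and asynchronous groups, 1 two-cell-like gene was called higher and none of the other 6 lists had a called member. Examples from the fit of the G1 libraries alone are Hist1h2bc (26.1 ± 0.161 against 15.6 ± 1.03 CPM), Ccne2 (49.7 ± 2.04 against 38.9 ± 0.164 CPM), Foxd3 (17.3 ± 1.91 against 28.9 ± 1.33 CPM) and Tubb5 (1047 ± 0.768 against 1450.1 ± 36.2 CPM).

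The feeder fibroblast markers were lower in late G1 than in early G1, with a median of -1.04 (0 of 25 called, 8 lower in the fit of the G1 libraries alone and 2 with the term, 10 lower adjusted over the list alone, camera adjusted p = 1.13e-17, adjusted p = 0.121 with an estimated correlation). The 6 largest falls under the rule for named genes, in the fit of the G1 libraries alone, were all matrix genes or their enzymes: Tnc (-2.11), Lox (-2.05), Col1a1 (-1.52), Col5a2 (-1.17), Fbln2 (-0.95) and Loxl2 (-0.89). The 6 largest rises under that rule were those of the neural transcription factor genes Pou4f3 (6.195 ± 0.203 against 2.84 ± 0.131 CPM) and Neurod1 (21.1 ± 0.618 against 10.6 ± 1.05 CPM), of Nectin4 (29.5 ± 0.131 against 15.0 ± 0.919 CPM), of C4a (0.96) and Plekhg6 (0.93) and of the mesoderm factor gene Mesp2 (0.92). The tubulin list lost its call without either mitotic library, early G1 replicate 1 or late G1 replicate 1 (camera adjusted p from 0.0583 to 0.148). The formative list lost it without early G1 replicate 2 or late G1 replicate 2 (0.0605 and 0.0825). The other 10 lists were not called (camera adjusted p from 0.0720 for LIF and STAT3 targets to 0.774 for heat shock), and median and mean differed in sign for Wnt targets (-0.048 and 0.050) and for actin and SRF or YAP targets (0.078 and -0.16).

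Over the whole 3 h after release, 1810 genes were called between mitotic and late G1 cells, 1038 higher and 772 lower. Plk1 fell from 158 ± 5.95 to 82.0 ± 0.717 CPM (adjusted p = 0.00434) and Esrrb from 579.5 ± 100.5 to 342 ± 13.0 CPM (adjusted p = 0.0354). Myc stood at 38.1 ± 2.71 against 17.2 ± 6.10 CPM and was not called in the fit of all 4 groups (adjusted p = 0.0990). Of 15 genes named in this comparison, 8 were called. Other fits called some of the rest: 2 in the fit of these 2 groups alone, 2 with the term for replicate 1 and 1 each by DESeq2 and limma voom. Myc may be among them. Of 62 G2 and M phase genes, 5 rose, 18 fell and 39 were not called (7 and 27 adjusted over the list alone). For G2 and M phase, camera gave adjusted p = 7.78e-05, or adjusted p = 0.468 with an estimated correlation. Of 30 p53 targets, 12 rose, 1 fell and 17 were not called (14 and 1 adjusted over the list alone). For p53 targets, camera gave adjusted p = 4.12e-05, or adjusted p = 0.212 with an estimated correlation. Of 50 G1 to S genes, 10 rose, 0 fell and 40 were not called (11 and 0 adjusted over the list alone). For G1 to S phase, camera gave adjusted p = 2.02e-05, or adjusted p = 0.0825 with an estimated correlation. Of 18 two-cell-like genes, 1 rose, 9 fell and 8 were not called (1 and 10 adjusted over the list alone). For two-cell-like, camera gave adjusted p = 4.12e-05, or adjusted p = 0.270 with an estimated correlation. Of 29 replication-dependent histone genes, 5 rose, 0 fell and 24 were not called (5 and 0 adjusted over the list alone). For histones, camera gave adjusted p = 0.0195, or adjusted p = 0.626 with an estimated correlation. In all, 12 lists were called, and none of them with an estimated correlation. The called lists included the fibroblast markers (3 of 25 lower). Median and mean of the glycolysis and hypoxia list, which was not called, differed in sign (-0.13 and 0.040). The Plk1 call was lost without late G1 replicate 1 or 2 (adjusted p = 0.0770 and 0.0814), and that of Esrrb without any mitotic, early G1 or late G1 library (adjusted p from 0.0786 to 0.239). Pou2f3 was lost without mitotic replicate 2 or either late G1 library (adjusted p from 0.0575 to 0.0902) and Gpnmb without late G1 replicate 1 (adjusted p = 0.0558). The feeder list lost its call without asynchronous replicate 1 or 2, mitotic replicate 2 or late G1 replicate 2 (camera adjusted p from 0.0893 to 0.224). The histone list lost its call without asynchronous replicate 1, mitotic replicate 1 or late G1 replicate 1 (0.0553 to 0.0831), cholesterol synthesis without mitotic replicate 1 (0.0831) and immediate early genes without mitotic replicate 2 (0.0528). The count of 1810 was 166 and 436 without mitotic replicates 1 and 2, 660 and 666 without early G1 replicates 1 and 2, 73 and 104 without late G1 replicates 1 and 2, and 5479 and 5546 without asynchronous replicates 1 and 2. The fit of these 2 groups alone called 3959 genes, no filter on low counts gave 3289, and leaving out replicate 1 of the mitotic and asynchronous groups gave 8525. The feeder and histone lists were then not called (camera adjusted p = 0.120 for each), nor with a term for those libraries (0.0990 and 0.186), which also ended the call of cholesterol synthesis (0.0681). The 2-group fit called 9 higher and 29 lower among G2 and M phase genes, 20 and 2 among G1 to S genes and 16 and 1 among p53 targets, and the term 11 and 27, 22 and 3 and 15 and 4.

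Of the 613 genes higher at 1 h than in mitotic cells, 534 were also called higher at 3 h, and of the 272 lower ones 238 were also lower. Egr1 stood at 8.39 ± 0.127 against 0.958 ± 0.195 CPM at 3 h, Fbxo5 at 99.1 ± 1.75 against 12.5 ± 0.274 CPM and Pou2f3 at 9.35 ± 1.23 against 1.51 ± 0.849 CPM, while Neat1 was at 24.6 ± 0.164 against 162 ± 15.3 CPM and Gpnmb at 4.02 ± 2.01 against 22.2 ± 5.57 CPM. Independent lists would share 33.3 higher and 10.99 lower genes. In 50 simulations in which no group was changed, at most 2 genes were shared. Few genes can be called without a change, so this count cannot show what shared libraries add when groups differ. The log2 fold changes at 1 h and 3 h correlated with r = 0.913 across genes and a covariance of 0.181. Simulations with the same spread in every library gave r = 0.502 and a covariance of 0.0312. The real biological coefficient of variation was 0.183 in the shared mitotic libraries, against 0.0506 and 0.0417 in early and late G1. Wider spread in the shared libraries raises r without any change between groups, so 0.502 is no baseline for 0.913. The mitotic libraries are too few to be split, so how much of the sharing comes from them cannot be told. The 772 genes shared in the same direction were 47 and 132 without mitotic replicates 1 and 2, 53 and 39 without early G1 replicates 1 and 2, 67 and 92 without late G1 replicates 1 and 2 and 3610 and 3673 without asynchronous replicates 1 and 2. DESeq2 gave 1163, and leaving out replicate 1 of the mitotic and asynchronous groups gave 6600. By edgeR's quasi-likelihood test 0 genes were called between 1 h and 3 h, with 724 unadjusted p under 0.05. None could therefore be called in opposite directions in the first hour and between 1 h and 3 h, and this overlap cannot show whether changes were transient. DESeq2 gave 11 genes called in opposite directions.

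Late G1 cells differed from asynchronous cells at 9305 genes, 4334 higher and 4971 lower, with 2181 and 3157 at least 2-fold apart. Myc was 16.3-fold higher in late G1 (38.1 ± 2.71 against 2.26 ± 1.70 CPM, adjusted p = 3.68e-04), Klf4 2.43-fold (183 ± 10.9 against 75.3 ± 12.7 CPM) and Ccne1 2.17-fold (348 ± 6.07 against 161 ± 39.3 CPM). Nanog was 1.24-fold higher (768 ± 11.6 against 619 ± 31.2 CPM, adjusted p = 0.0430), a call that was lost without any of the mitotic, early G1 or late G1 libraries (adjusted p from 0.0535 to 0.196), without the filter on low counts (adjusted p = 0.0512) and in the fit of the 2 groups alone (adjusted p = 0.138). Plk1 fell from 137 ± 10.6 to 82.0 ± 0.717 CPM. Ccnb1 fell from 138 ± 2.37 to 97.2 ± 5.08 CPM, a call lost without late G1 replicate 1 (adjusted p = 0.0891) and in the fit of the 2 groups alone (adjusted p = 0.0511). Pou5f1 stood at 1868 ± 28.2 against 1772 ± 423 CPM, Sox2 at 254 ± 15.0 against 281 ± 42.9 CPM and Esrrb at 342 ± 13.0 against 314 ± 70.5 CPM, and none of these was called. The sign of all 3 turned without asynchronous replicate 1, to log2 values of -0.14, 0.018 and -0.086. Asynchronous replicates 1 and 2 stood at 1472 and 2071 CPM for Pou5f1, 312 and 251 CPM for Sox2 and 264 and 364 CPM for Esrrb. The late G1 means lay between them, so the change depended on the asynchronous library.

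Genes of the G1 to S transition were higher in late G1: of 50, 27 rose and 2 fell (28 and 2 adjusted over the list alone), with camera adjusted p = 1.92e-05 and adjusted p = 0.0351 with an estimated correlation. Ccne2 stood at 49.7 ± 2.04 against 9.49 ± 3.31 CPM and Cdc6, a replication licensing factor gene, at 147 ± 3.63 against 43.3 ± 9.16 CPM. Ribosome biogenesis genes were higher as well (29 of 40 rose and 1 fell, 31 and 2 adjusted over the list alone, camera adjusted p = 1.11e-08, adjusted p = 0.0351 with an estimated correlation), with Ddx21 at 739.5 ± 24.8 against 203 ± 49.7 CPM and Nop58 at 661 ± 19.1 against 325 ± 17.3 CPM. Glycolysis and hypoxia genes were lower (27 of 29 fell and none rose, 28 lower adjusted over the list alone, camera adjusted p = 3.51e-14, adjusted p = 0.0351 with an estimated correlation), with Ankrd37 at 6.11 ± 0.253 against 53.5 ± 5.54 CPM. Feeder fibroblast markers moved with them (24 of 25 fell and none rose, 24 lower adjusted over the list alone, camera adjusted p = 3.51e-14, adjusted p = 0.0458 with an estimated correlation), and the largest falls under the rule for named genes were Lyz2, with 0 counts in late G1 and at least 84.6-fold lower, Col3a1 (-8.28), Postn (-7.78), Col1a2 (-7.50), Ccdc80 (-6.68) and Col8a1 (-6.61). The largest rises under it were Cyp1a1 (21.9 ± 1.23 against 0.130 ± 0.0409 CPM), Synpo2l (5.05), Egr1 (8.39 ± 0.127 against 0.281 ± 0.110 CPM), Spry4 (36.0 ± 1.11 against 1.35 ± 0.671 CPM), Fam196a (4.36) and Nt5e (4.14).

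Further lists were called against asynchronous cells and lost with an estimated correlation. Of 29 immediate early genes, 17 rose, 4 fell and 8 were not called (17 and 4 adjusted over the list alone). For immediate early, camera gave adjusted p = 0.00306, or adjusted p = 0.386 with an estimated correlation. Srf and Btg2 rose 3.23- and 2.76-fold. Of 19 formative and primed genes, 10 rose, 5 fell and 4 were not called (10 and 5 adjusted over the list alone). For formative and primed pluripotency, camera gave adjusted p = 0.0412, or adjusted p = 0.386 with an estimated correlation. Dnmt3b, a DNA methyltransferase gene, stood at 340.3 ± 5.46 against 74.9 ± 8.55 CPM. Of 30 p53 targets, 14 rose, 3 fell and 13 were not called (14 and 3 adjusted over the list alone). For p53 targets, camera gave adjusted p = 0.0147, or adjusted p = 0.386 with an estimated correlation. Plk2 stood at 266 ± 1.56 against 34.6 ± 7.49 CPM. Of 30 core and naive pluripotency genes, 16 rose, 5 fell and 9 were not called (16 and 6 adjusted over the list alone). For core and naive pluripotency, camera gave adjusted p = 0.0321, or adjusted p = 0.386 with an estimated correlation. Nr0b1 stood at 114 ± 4.30 against 16.6 ± 1.53 CPM. Of 62 G2 and M phase genes, 6 rose, 25 fell and 31 were not called (6 and 25 adjusted over the list alone). For G2 and M phase, camera gave adjusted p = 0.0147, or adjusted p = 0.565 with an estimated correlation. Top2a, the mitotic topoisomerase gene, stood at 349 ± 11.1 against 1183 ± 207 CPM and Cdca2 at 66.5 ± 3.91 against 171 ± 1.26 CPM. In the mitotic libraries Top2a was lower than in late G1, at 140 and 121 CPM, while Cdca2 was higher, at 104 and 90.2 CPM. Of 12 tubulins, 1 rose, 8 fell and 3 were not called (1 and 8 adjusted over the list alone). For tubulins, camera gave adjusted p = 0.00535, or adjusted p = 0.468 with an estimated correlation. Tubb5 stood at 1047 ± 0.768 against 3702 ± 485 CPM. It had been lower in the mitotic libraries (535 and 539 CPM) and higher in early G1 (1476 and 1424 CPM) than in late G1.

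The integrated stress response was lower: of 28 genes, 4 rose, 18 fell and 6 were not called (5 and 19 adjusted over the list alone). For integrated stress response, camera gave adjusted p = 3.70e-04, or adjusted p = 0.386 with an estimated correlation. Ddit4 stood at 92.0 ± 0.321 against 532 ± 19.1 CPM. Of 83 ribosomal protein genes, 4 rose, 51 fell and 28 were not called (6 and 53 adjusted over the list alone). For ribosomal proteins, camera gave adjusted p = 3.11e-06, or adjusted p = 0.565 with an estimated correlation. Rpl36 stood at 83.6 ± 0.657 against 289.8 ± 95.9 CPM. Of 30 genes of cohesin, condensin, CTCF and acetylation, 12 rose, 4 fell and 14 were not called (12 and 4 adjusted over the list alone). For cohesin and acetylation, camera gave adjusted p = 0.0147, or adjusted p = 0.565 with an estimated correlation. The condensin subunit gene Ncapg2 stood at 116 ± 3.03 against 46.1 ± 7.78 CPM. The other 8 lists were not called (camera adjusted p from 0.0850 for heat shock to 0.731 for replication-dependent histones). Without asynchronous replicate 1 the core pluripotency, formative and G2 and M phase lists lost their calls (camera adjusted p = 0.145, 0.0747 and 0.118), and without asynchronous replicate 2 the cohesin list did (0.141). The core pluripotency, formative and G2 and M phase lists also lost their calls with a term for replicate 1 of the mitotic and asynchronous groups (0.132, 0.118 and 0.132) and without both of those libraries (0.158, 0.104 and 0.155). In the fit of these 2 groups alone, 2 higher and 15 lower were called among G2 and M phase genes, 10 and 5 among core pluripotency genes, 7 and 2 among cohesin and acetylation genes, 2 and 14 in the integrated stress response, 22 and 1 among G1 to S genes and 2 and 36 among ribosomal protein genes. The term gave 14 and 26 for G2 and M phase, 20 and 4 for cohesin and acetylation, 16 and 7 for p53 targets and 31 and 4 for G1 to S. The count of 9305 was 5096 and 5166 without late G1 replicates 1 and 2. At 1 h the picture against asynchronous cells was close in number, with 8784 genes called, 4064 higher and 4720 lower, and Myc at 42.4 ± 1.62 against 2.26 ± 1.70 CPM and Klf4 at 211 ± 2.94 against 75.3 ± 12.7 CPM. Nanog was also higher (828 ± 2.95 against 619 ± 31.2 CPM), a call lost without either early G1 library (adjusted p = 0.0873 and 0.0977) and in the fit of the 2 groups alone (adjusted p = 0.0758). The p53 list was called (camera adjusted p = 0.0447, adjusted p = 0.379 with an estimated correlation), but not without early G1 replicate 1 or either mitotic library (0.0729, 0.0505 and 0.0501), with scaling by total counts (0.0538) or with the term for replicate 1 (0.102). Cholesterol synthesis, not called, had a median of 0.049 and a mean of -0.031. The count of 8784 was 4793 and 4186 without early G1 replicates 1 and 2 and 5626 in the fit of the 2 groups alone, and 13517 when replicate 1 of the mitotic and asynchronous groups was left out. Of its 12 called lists, 3 were called with an estimated correlation: glycolysis and hypoxia (27 of 29 fell, adjusted p = 0.0350 with an estimated correlation), ribosome biogenesis (30 of 40 rose, adjusted p = 0.0350 with an estimated correlation) and G1 to S (28 of 50 rose, 17 in the fit of the 2 groups alone, adjusted p = 0.0487 with an estimated correlation). Feeder fibroblast markers moved with these lists: 24 of 25 fell and none rose (24 lower adjusted over the list alone), with a median of -3.89, camera adjusted p = 4.54e-13 and adjusted p = 0.0540 with an estimated correlation.

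Many of the differences between mitotic and asynchronous cells were also called at 3 h. The mitotic and G1 libraries shared the synchronisation and held 81.5 to 155 CPM of feeder markers, against 1905 and 1933 CPM in the asynchronous ones. Persistence from the arrest therefore cannot be told apart from traits of the asynchronous libraries. Of the 3487 genes higher in mitotic than in asynchronous cells, 2645 were higher in late G1, and of the 4280 lower ones 3298 were lower. Under the rule for named genes, those with the largest smaller change of both comparisons included Cyp1a1 and Synpo2l among the higher ones and Postn, Lox and Col1a2, all feeder markers, among the lower ones. Independent lists would share 791 higher and 1114 lower genes. At most 1 gene was shared in 50 simulations of unchanged groups, in which few genes can be called, so that count is no measure of the excess. The log2 fold changes had a covariance of 0.626 (r = 0.856 across genes). Simulations with the same spread in every library gave 0.0313 (r = 0.502). The real biological coefficient of variation was 0.292 in the shared asynchronous libraries, against 0.183 in mitotic cells and 0.0417 in late G1. Wider spread in the shared libraries raises both values without any change between groups, so the simulated ones are no baseline. The 2 asynchronous libraries are too few to be split, so how much of the sharing comes from them cannot be told. The 5943 shared genes were 3930 without mitotic replicate 1, 3698 and 3730 without late G1 replicates 1 and 2 and 9740 when replicate 1 of both the mitotic and asynchronous groups was left out.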

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

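The term for replicate 1 of the mitotic and asynchronous groups, leaving out both of these libraries, and lists without feeder genes were chosen after seeing the data; the others were set before. Where a value moved, the cause was not tested unless stated. Scaling by DESeq2's size factors or by total counts, limma voom and a filter of 1 CPM kept every gene count within 1.5 times, and scaling moved the median of all genes by less than 0.1 on the log2 scale.

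Genes called between early G1 and mitotic cells (885) were 1410 by DESeq2, 2362 without a low-count filter, 2759 in the fit of the 2 groups, 5882 with the added term, 7918 without both replicate 1 libraries and 42 to 4518 when single libraries were left out. Between early and late G1 (0 by edgeR) these counts were 27, 58, 1493, 16, 1518 and 0 to 25. For late G1 against mitotic cells (1810), no filter gave 3289, the 2 groups 3959, the term 6593, leaving out both 8525 and single libraries 73 to 5546. For mitotic against asynchronous cells (7767) the 2 groups gave 3883, leaving out both 11700 and single libraries 4737 to 10382. For late G1 against asynchronous cells (9305) leaving out both gave 13664 and single libraries 5096 to 11489. For early G1 against asynchronous cells (8784) the 2 groups gave 5626, leaving out both 13517 and single libraries 4186 to 11237. Genes that differed between any states (9265) were 15268 without both and 6067 to 12556 without single libraries. The fits with fewer groups take the spread from fewer libraries, and the asynchronous ones had the widest.

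Genes shared by 1 h and 3 h after release (772) were 1163 by DESeq2, 4904 with the term, 6600 without both and 39 to 3673 without single libraries. Genes shared by mitotic and late G1 cells against asynchronous ones (5943) were 9740 without both and 3698 to 8459 without single libraries. Genes called in opposite directions (0) were 11 by DESeq2, 8 with the term, 406 without both and 0 to 11 without single libraries.

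With an estimated correlation, lists called were 2 for mitotic against asynchronous cells, 0 for early G1 against mitotic, 0 for late against early G1, 0 for late G1 against mitotic, 4 for late G1 and 3 for early G1 against asynchronous cells. In that order, of the lists called with the preset one, fry did not call 3, 5, 9, 4, 0 and 0, and it called 2 in all for late against early G1. The added term ended 1, 0, 0, 3, 3 and 2 list calls, leaving out both libraries 2, 0, 0, 2, 3 and 0, scaling by total counts 0, 1, 0, 0, 0 and 1, and the replicate block 0, 0, 0, 0, 1 and 1. In early G1 against asynchronous cells the term ended the call of the formative list (camera adjusted p = 0.0547). Leaving feeder genes out of the other lists took 2 genes from the actin list and none from the rest, so it tested that list alone, which kept its calls (median -0.29 in late G1 against mitotic cells, where it had been -0.35).

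Signs turned only for genes that were not called. With the added term, Ccne1 in early G1 against mitotic cells (0.11) had -0.044. Against asynchronous cells, Esrrb and Pou5f1 in late G1 (0.12 and 0.076) had -0.064 and -0.041, and Pou5f1 in early G1 (0.069) had -0.048. Without both replicate 1 libraries these last 3 had -0.086, -0.15 and -0.15, with edgeR adjusted p = 0.0386 and 0.0304 for Pou5f1 in late and early G1. Sox2 then had 0.052 in mitotic and 0.018 in late G1 against asynchronous cells (-0.16 and -0.15). In late G1 against mitotic cells Sox2 (0.012) had -0.035 and Klf4 (0.086) had -0.075.

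Ranges over single libraries that crossed 0 were as follows. Sox2 went from -0.31 to 0.0086 in mitotic, -0.30 to 0.018 in late G1 and -0.059 to 0.26 in early G1 against asynchronous cells, and from -0.049 to 0.071 in late G1 against mitotic cells. Pou5f1 went from -0.067 to 0.084 in late against early G1, and against asynchronous cells from -0.14 to 0.34 in late and -0.15 to 0.33 in early G1. Klf4 went from -0.075 to 0.26 in late G1 against mitotic cells. Esrrb in late and Plk1 in early G1 against asynchronous cells went from -0.086 to 0.37 and from -0.13 to 0.017.

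The labels tie no replicate number to a clone, and not every pair of groups shared its replicate deviations, so the numbers were not taken to pair the samples. The correlation of these deviations was 0.621 between asynchronous and mitotic cells, which did share a difference between replicates, and -0.365 and 0.0447 between asynchronous cells and early and late G1, -0.135 and 0.0572 between mitotic cells and early and late G1, and -0.0437 between early and late G1. With the number as a block, 7889, 803, 0, 1744, 9430 and 8921 genes were called for mitotic against asynchronous, early G1 against mitotic, late against early G1, late G1 against mitotic, and late and early G1 against asynchronous cells. The block ended the calls of Slc7a11 in early G1 against mitotic cells (edgeR adjusted p = 0.0586), of Nanog and the formative list in late G1 against asynchronous cells (edgeR adjusted p = 0.0594, camera adjusted p = 0.0605) and of p53 targets in early G1 against asynchronous cells (camera adjusted p = 0.0532). At this depth the floor of 3 counts lay at 0.116 to 0.152 CPM.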

Other observations

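Small nucleolar RNA genes, whose products guide the modification of ribosomal RNA, stood out among the genes that rose after mitosis. Of 87 tested, 26 were called higher in early G1 than in mitotic cells (29.9%, against 3.21% of all tested genes) and 0 lower (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.34e-17), and 36 were higher in late G1. Small nucleolar RNA genes lie inside introns and exons of host genes, and where their reads came from was not examined. In libraries selected for poly(A) RNA such reads need not measure mature small RNAs. Fisher's exact test, here and below, takes genes as independent. Genes that share a host are not, so its p-values may be too small. Host genes moved too: of 15 hosts, a list written after others had been noticed, 12 were lower in mitotic than in asynchronous cells (median -1.99, camera adjusted p = 4.77e-08, adjusted p = 0.124 with an estimated correlation) and 7 were higher in early G1 than in mitotic cells (median 0.94, camera adjusted p = 3.72e-09, adjusted p = 0.119 with an estimated correlation). Antisense (40 of 517), lincRNA (39 of 632) and processed transcript genes (28 of 252) were also called higher more often than the 3.21% of all genes (Fisher's exact adjusted p = 9.07e-07, 0.000207 and 4.09e-08), and processed pseudogenes less often (14 of 2039, adjusted p = 8.54e-15).

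Feedback targets of ERK signalling ranked upward in each synchronised state against asynchronous cells, comparisons in which 23, 24 and 24 of 25 feeder fibroblast markers fell (medians -4.22, -3.89 and -4.61 for mitotic cells, early and late G1). Of 14 tested members, with Spry4 and other noticed genes left out, 9 rose and 1 fell in mitotic cells (median 0.84, camera adjusted p = 0.000962, adjusted p = 0.118 with an estimated correlation), 10 rose and none fell in early G1 (median 1.51) and 10 rose and none fell in late G1 (median 1.38). For both G1 states the list was called as well (camera adjusted p = 0.000323 and 0.000528) and the call was lost in the same way (adjusted p = 0.118 with an estimated correlation in each). The medium held a MEK inhibitor per the labels. Of 5 targets of the aryl hydrocarbon receptor besides Cyp1a1, 1 rose and 1 fell in mitotic against asynchronous cells and the list was not called in any comparison (camera adjusted p from 0.231 to 0.902). Of 22 germ layer and extraembryonic genes, 8 rose and 9 fell in late G1 against asynchronous cells (11 and 9 adjusted over the list alone, camera adjusted p = 0.531).

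Every test in the paragraphs that follow was chosen after the result was seen, except that of gene length. The first pattern is the difference between replicates 1 and 2 that the asynchronous and mitotic groups shared and the G1 groups lacked. Crossed numbers in G1 would need the 41 genes at least 4-fold apart in asynchronous cells to differ in the opposite direction, and their median signed difference was 2.50 in asynchronous, 1.82 in mitotic and -0.0424 in early G1. On a scale from mitotic replicate 1 (0) to replicate 2 (1), the 31 of these genes that also differed at least 2-fold in the same direction in mitotic cells had medians in the G1 libraries from 0.502 to 0.582, as a pool of both clones could give, but 10 of them on the X and Y chromosomes had 0.579 to 0.805 and the other 21 had 0.465 to 0.491. All 9 tested Y-linked genes at least 2-fold higher in mitotic replicate 1 than 2, of which 2 are among the 31, had a median position of 0.869 (quartiles 0.773 and 1.04), nearer to the source of replicate 2 than to an even pool, while Zfy2 and Uba1y lay at 0.473 and 0.540. Neither explanation accounts for all of these genes, what the G1 libraries were made from stays open, and a biological difference between the clones was not tested.

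The second pattern is the presence of fibroblast transcripts (Col1a1 at 509 and 554 CPM in asynchronous libraries) and macrophage transcripts (the abundant Lyz2 at 28.7 and 30.8 CPM in mitotic, 9.44 and 14.7 CPM in asynchronous and at most 0.756 CPM in G1 libraries, while Spp1 and Laptm5 were abundant in all 8). Feeder fibroblasts collected with the asynchronous cells are a candidate source of the former, which was noticed on the 25 fixed markers. Of 45 further fibroblast genes outside every fixed list, 33 were higher in both asynchronous libraries than in all 6 others. This share (73.3%) lay just above the bound of 70% set for the test. Chance would give 3.57% if genes were independent and the 8 libraries interchangeable, and neither holds. Of all 19101 tested genes, 3298 were called lower in both mitotic and late G1 cells than in asynchronous ones. The share of all tested genes that were highest in both asynchronous libraries was not computed, so the markers have no fitting baseline. Sparc, abundant in all 8 libraries, was among the 12 further fibroblast genes without this pattern. Other fibroblast-like cells were not told apart from feeders. Macrophages shaken off with the mitotic cells may have added the macrophage transcripts. Of 35 markers, 65.7% were higher in both mitotic libraries than in all 4 G1 libraries, between the bounds of 50% and 70% set for the test. The share by chance, 6.67%, rests on the same assumptions as above. Of the 35, 19 were higher in both asynchronous libraries than in all 4 G1 libraries. Shaken-off macrophages therefore cannot be told apart from other sources, among them one shared with the asynchronous cells. Of all 35 markers, raised or not, 2 (5.71%) were at least 2-fold apart between the mitotic replicates, so most stood alike in both. Of 12037 genes with higher levels, 194 were that far apart. The pattern had been noticed on Lyz2 and other genes already alike in both mitotic replicates, so a low share was foreseeable. It therefore cannot decide on a difference between the cell sources of replicates 1 and 2. Another source of the G1 libraries stays open too.

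The third pattern is the level of glycolysis and hypoxia genes in asynchronous cells, whose sum was 22531 and 26941 CPM there and 9908 to 11015 CPM elsewhere. RNA of feeder fibroblasts could raise them, and a test on the change from early to late G1, where fibroblast markers had a median of -1.04 and these genes one of -0.14, was void because only 3.16% of the asynchronous excess of feeder RNA was left in early G1. The asynchronous state and the feeder RNA therefore cannot be told apart for these genes. Cell density and oxygen, which the labels do not record for each sample, were not tested.

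Before the data were examined, long genes were predicted to regain their transcripts later than short ones, with a rank correlation of gene span and change from early to late G1 above 0.1. Over 10789 protein-coding genes, which are not independent replicates, Spearman's rho was -0.106, so the data did not bear this out. Genes spanning over 100 kb had a median change of -0.094 (1328 genes) and those under 10 kb one of 0.0013 (2443 genes).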
